A study of Rattus norvegicus with 12 samples.

How the data were processed

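RNA of rat astrocytes was measured on Illumina RatRef-12 bead arrays, 12 in all: astrocytes kept for 6 h or 24 h in medium conditioned by cells making α-synuclein or lacZ, 3 arrays per group. Per the labels, scanned images were processed with the R package beadarray; the version, background correction and normalization are not given in the sources used here. The deposited values are log2 intensities, read as such from their range of 4.39 to 14.21. They had been normalized between arrays before deposition, since the sorted values of any array differ from the mean over arrays by at most 0.0437. They were used without further transformation.

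The probe annotation gives 1 gene symbol for 13793 of the 22523 probes and none for 8730; 425 genes have more than 1 probe. Glul has no probe under that symbol in the annotation used and is not analysed here. All probes were tested. A background ceiling of 5.45 was set, after the values were seen, at the mode of the dim probes (4.99) plus 3 standard deviations (0.152 each), and 10213 probes (45.3%) never exceeded it. The ceiling serves to state folds as lower bounds when every array of a group lies at or below it: the fold is then taken against the ceiling.

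A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), leaving 8 residual degrees of freedom and a prior of 10.2. It gave 5 two-sided comparisons: α-synuclein against lacZ medium at 6 h and at 24 h, the difference between these effects, and 24 h against 6 h within each medium. P-values were adjusted by the Benjamini-Hochberg method over the 22523 probes of each comparison, at a threshold of 0.05. "Rose" and "fell" are used for what passed it. With 3 arrays against 3 an exact two-sided permutation test cannot give a p below 0.1, so that no such test could pass. Overlap of the 6 h and 24 h calls was set against the number expected for independent calls.

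Gene lists, 28 for pathways and 6 for markers of other cell types, were written from general knowledge before the data were examined, as were the groups, comparisons, tests, alternatives and the rule for naming genes. Each list was tested with camera from limma (preset correlation 0.01) on the brightest probe per gene, with adjustment over the 34 lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance or, in its mixed form, in either direction, without comparing them with other genes. Counts of members that passed are given over all probes and adjusted over the list alone. Lists share some genes, and many members are also expressed by astrocytes.

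Genes are named by rule: at each time the 15 largest rises and 10 largest falls that passed and whose arrays did not overlap, for each list up to 4 members of smallest p and any member that passed, the 10 smallest p of the difference between times, the 8 largest rises and falls of each time course, and always a fixed set that includes Gfap, Vim, Aqp4, Glul, Slc1a2, Slc1a3, Actb and Gapdh. Probes had to carry exactly 1 symbol. Positions are those of the GRCr8 annotation.

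The calculation was tested on simulated data with known changes. Changed probes were drawn from those with a mean above the background ceiling, and each probe had independent normal noise of the same spread in all groups. Recovery of dimmer probes and unequal spread between groups were therefore not tested. At a log2 change of 0.5 it recovered 94% of changed probes at 6 h, 89.6% at 24 h, 59.7% for the difference between times and 91% in each time course, and at least 97% at a change of 1. False calls were 4.5% to 7.5%.

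Alternatives tried were quantile normalization, median centring, only probes above the median or above the upper quartile of mean intensity, only the arrays compared, the replicate number as a block, limma-trend, array weights, 1 probe per gene, a two-sample test per probe, a minimum change of 1.5-fold, an unadjusted p threshold of 0.01 for the overlap, and each array left out in turn. Those added after the data were seen left out the 2 arrays of lowest weight or kept only probes above background. Replicate numbers did not pair the arrays across all groups: an array correlated best with its own number in 11 of 36 cases, where chance gives 12. Between the media at 6 h, deviations from the group means correlated at 0.35 for replicate 1, 0.055 for replicate 2 and 0.144 for replicate 3. A feature shared by the 6 h arrays of replicate 1 is therefore not excluded. The arrays carry no batch labels, and a difference in handling between 6 h and 24 h arrays cannot be told apart from time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.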

Results

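Messenger RNA was measured in rat astrocytes, the main supporting glia of the brain, kept in medium taken from other cells that made either α-synuclein, the protein that forms aggregates in Parkinson disease, or lacZ, the bacterial β-galactosidase used as the control protein. Exposure lasted 6 h or 24 h. The 4 groups (lacZ and α-synuclein medium, each at 6 h and 24 h) hold 3 arrays each, 12 arrays in all. Every array gave a log2 intensity for 22523 probes, of which 13793 carry 1 gene symbol, for 13337 genes. Intensities ran from 4.39 to 14.21, each array had a median of 5.38, and 47.7% to 47.8% of probes lay above a background ceiling of 5.45. Arrays of 1 group correlated with each other at 0.996 to 0.999 across probes, which are not independent replicates, and the number of arrays limits the precision. The first principal component held 60.2% of the variance and separated the 24 h arrays from the 6 h arrays, and the second held 30% and separated α-synuclein medium from lacZ medium at each time. Changes below are log2 differences between means of 3 and 3 arrays, ± standard error (SE), with adjusted p-values from limma. Where all arrays of one group lay at or below the ceiling, the fold is given as a lower bound, and a log2 difference beside it is the fitted value, not a bound. Whether the replicates come from separate cultures is not given in the sources used here, so the p-values measure only the spread between these samples.

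The first comparison asks how the astrocyte cultures differ after 6 h in medium from cells making α-synuclein and in medium from cells making lacZ. The arrays do not measure α-synuclein in the medium, and other differences between the media cannot be told apart from it. Nor do they tell which cells of a culture made a transcript. The 15 largest rises that the naming rule picks included chemokine genes and Il1b. Ccl20, a chemokine that attracts dendritic cells and T cells, was 114-fold higher in α-synuclein medium (log2 change 6.83 ± 0.289, n = 3 and 3, adjusted p = 4.7e-12). Cxcl6, which attracts neutrophils, was at least 46.6-fold higher, since its lacZ arrays lay at background (5.64 ± 0.087, adjusted p = 1.43e-18). Il1b, the inflammatory cytokine interleukin-1β, was at least 23.6-fold higher, and Lcn2, an iron-scavenging protein that marks reactive astrocytes, was 8.95-fold higher (3.16 ± 0.119, adjusted p = 7.54e-13). The falls were smaller: Pik3ip1, an inhibitor of phosphoinositide 3-kinase, was 2.52-fold lower (adjusted p = 2.87e-10), and Epha4, a receptor for ephrins, changed by -0.97 ± 0.079 (adjusted p = 9.11e-08).

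In all, 964 of 22523 probes changed at 6 h, 565 higher and 399 lower in α-synuclein medium. Of the 92 probes that changed at least 2-fold, 89 were higher and 3 lower, and 13 were at least 8-fold higher. The 3 arrays of one medium did not overlap the 3 of the other for 3691 probes, 16.4% of all, where chance gives 10%. On the GRCr8 assembly Ccl20 (gene 29538) lies on chromosome 9 at 91837139 to 91839736, Il1b (gene 24494) on chromosome 3 at 137030200 to 137036581, Lcn2 (gene 170496) on chromosome 3 at 36078432 to 36081851, and Cxcl6 (gene 60665) on chromosome 14 at 17594959 to 17596417.

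Of 34 gene lists fixed before the data were examined, 14 stood higher and 1 lower than other genes at 6 h (camera), and 12 of these calls held with an estimated correlation. The strongest was the list of NF-kB pathway feedback genes, which the inflammatory transcription factor NF-kB induces and which restrain or relay its signal. Of its 17 measured members 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 change of 1.26 (adjusted p = 6.24e-48). Among them were Cd83, an activation marker of dendritic cells (4.74 ± 0.08), Nfkbia, the inhibitor of NF-kB (2.71 ± 0.082), and Birc3, an inhibitor of apoptosis (2.37 ± 0.066). Of 32 chemokines 16 rose and 0 fell (19 and 0 adjusted over the list alone, adjusted p = 2.12e-32). They included Cxcl2 (at least 23.2-fold), Ccl3 (at least 12.9-fold), Ccl5 (at least 11.7-fold), and Cx3cl1, the chemokine that microglia sense (3.20 ± 0.083). Cxcl1 rose by 4.25 ± 0.197, and its mean of 13.95 in α-synuclein medium lay near the highest value of any probe, 14.21. Of 37 cytokines 11 rose and 0 fell (12 and 2 adjusted over the list alone, adjusted p = 7.94e-08), among them Il1a (at least 8.62-fold), the macrophage growth factor Csf1 (2.39 ± 0.086) and Il6 (1.72 ± 0.093). Tnf, the tumour necrosis factor gene, stood at 0.19 with an adjusted p of 0.111 and did not pass.

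Interferon response genes rose in 23 of 39 cases and none fell (29 and 0 adjusted over the list alone, median 0.49, adjusted p = 3.53e-31), with the guanylate-binding proteins Gbp5 (2.95 ± 0.079) and Gbp2 (2.46 ± 0.076) as examples. α-Synuclein 6 h replicate 1 stood above its group here, with a mean of 8.27 over the 33 interferon response members above background, against 7.68 and 7.62 for the others and 6.85 to 6.94 in lacZ medium. The call held without it. Of 31 antigen presentation genes 16 rose and 0 fell (19 and 1 adjusted over the list alone, adjusted p = 1.33e-18), including the peptide transporter Tap1 (1.07 ± 0.071). The list of pattern recognition and interleukin receptors had 5 rises among 28 and 0 falls (6 and 0 adjusted over the list alone, adjusted p = 2.35e-05), with the bacterial sensor Tlr2 at 2.64 ± 0.108. Of 18 adhesion and leukocyte trafficking genes 6 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 5.03e-06), with Vcam1 at 3.06 ± 0.103 and Icam1 at 1.83 ± 0.082, both ligands for leukocyte integrins. JAK-STAT3 response genes (5 higher and 1 lower of 22, 7 and 1 adjusted over the list alone, adjusted p = 0.000248) and p53 and cell death genes (7 and 1 of 25, 11 and 1 adjusted over the list alone, adjusted p = 4.76e-05) also stood higher. So did matrix proteases and inhibitors (6 and 0 of 29, 7 and 2 adjusted over the list alone, adjusted p = 0.0021), with the metalloproteinase Mmp3 at least 2.78-fold higher.

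Both reactive astrocyte lists stood higher. The pan-reactive list had 6 rises and 0 falls among 21 genes (7 and 2 adjusted over the list alone, adjusted p = 0.00079), and the A1-type list 4 and 0 among 10 (5 and 0 adjusted over the list alone, adjusted p = 7.15e-06). Gfap, the astrocyte intermediate filament, stood at -0.18 (adjusted p = 0.213), Vim at 0.04 (adjusted p = 0.885) and the water channel Aqp4 at 0.27 (adjusted p = 0.311), none of which passed. The homeostatic astrocyte list had 0 rises and 1 fall among 37 genes (0 and 1 adjusted over the list alone) and did not pass (adjusted p = 0.0689). It passed downward without lacZ 6 h replicate 2 (adjusted p = 0.00936) or 3 (0.0309) and without α-synuclein 6 h replicate 1 (0.0256) or 3 (0.0309). Markers of microglia, the macrophages of the brain, were higher in 4 of 37 cases and lower in 0 (6 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.0787). The microglia list passed upward without lacZ 6 h replicate 1 (adjusted p = 0.00233) and without α-synuclein 6 h replicate 3 (adjusted p = 0.0021). Complement and acute phase genes passed without lacZ 6 h replicate 1 (adjusted p = 0.0211) or α-synuclein 6 h replicate 3 (0.028). Cell cycle genes did so without lacZ 6 h replicate 2 (0.018) or α-synuclein 6 h replicate 1 (0.0242). Antioxidant and NRF2 genes did so without lacZ 6 h replicate 3 (0.0226) or α-synuclein 6 h replicate 2 (0.0113). Ribosomal proteins passed without lacZ 6 h replicate 1 (0.0487). None of these lists passed with all arrays. Eicosanoid and nitric oxide genes (6 and 0 of 25, 6 and 2 adjusted over the list alone) passed with adjusted p = 0.00761, but adjusted p = 0.217 with an estimated correlation. Immediate early and MAPK feedback genes passed with adjusted p = 7.15e-06 and lost the call at adjusted p = 0.0589 with an estimated correlation. Their members went both ways, 8 higher and 4 lower of 35 (12 and 5 adjusted over the list alone): Junb rose (1.54 ± 0.087), whereas Jun (-0.54 ± 0.065) and Fos (-0.50 ± 0.062) fell. The lysosome and autophagy list stood lower with 1 fall among 36 genes (0 and 1 adjusted over the list alone, adjusted p = 0.000983), and adjusted p = 0.0682 with an estimated correlation. Estimating the spread from the 6 arrays at 6 h alone reduced the count of changed probes from 964 to 538. The same step at 24 h raised the count from 4348 to 5132. Part of the 964 thus depends on a spread pooled with the 24 h arrays.

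**Figure D1:**
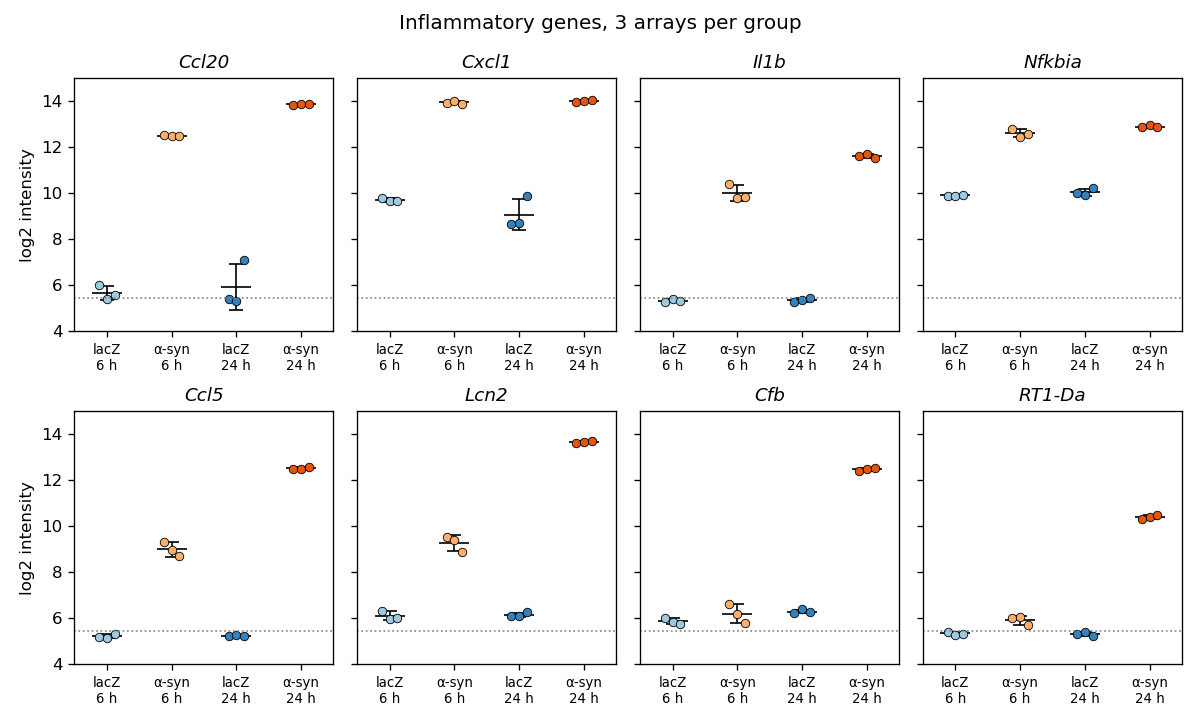
Log2 intensity on each array (dots) with the group mean and standard deviation (bars, n = 3) of 8 inflammatory genes in lacZ and α-synuclein medium at 6 h and 24 h; the dotted line is the background ceiling of 5.45. Ccl20 averaged 5.68 in lacZ medium and 12.51 in α-synuclein medium at 6 h, while RT1-Da averaged 5.92 at 6 h and 10.41 at 24 h in α-synuclein medium.

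After 24 h the same question is asked of the longer exposure. Chemokine genes were again among the largest rises. Cxcl6 was 255-fold higher in α-synuclein medium (log2 change 7.99 ± 0.087, n = 3 and 3, adjusted p = 2.56e-21), Ccl20 was 242-fold higher (7.92 ± 0.289, adjusted p = 8.03e-14) and Lcn2 was 182-fold higher (7.51 ± 0.119, adjusted p = 3.27e-19). Cfb, factor B of the alternative complement pathway, was 73-fold higher (6.19 ± 0.134, adjusted p = 2.65e-17). The class II antigen presentation gene RT1-Da was at least 31.1-fold higher (adjusted p = 4.46e-19). Acta1, skeletal muscle α-actin, had the largest fall, 13.8-fold (-3.78 ± 0.104, adjusted p = 1.15e-15), followed by Omd, a small matrix proteoglycan (-3.21 ± 0.116, adjusted p = 6.83e-14).

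At 24 h 4348 probes changed, 1889 higher and 2459 lower in α-synuclein medium, and 486 of them by at least 2-fold (316 higher, 170 lower). At least 8-fold changes numbered 41 higher and 3 lower. The arrays of the 2 media did not overlap for 7847 probes, 34.8% of all, where chance gives 10%. Cfb (gene 294257) and RT1-Da (gene 294269) lie on chromosome 20 at 3975271 to 3981138 and 4515393 to 4520387, and Acta1 (gene 29437) on chromosome 19 at 68781168 to 68784194. Of the 34 lists 15 stood higher and 3 lower, and 10 of these calls held with an estimated correlation.

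Antigen presentation genes rose almost throughout: 29 of 31 were higher and 0 lower (30 and 0 adjusted over the list alone), with a median log2 change of 1.15 (adjusted p = 2.97e-33). Besides RT1-Da they included Cd74, the invariant chain of class II molecules (at least 5.05-fold, 2.79 ± 0.063), RT1-Ba (at least 4.97-fold) and Psmb8, a subunit of the immunoproteasome (1.83 ± 0.107). Of 32 chemokines 22 rose and 0 fell (22 and 0 adjusted over the list alone, median 2.10, adjusted p = 3.86e-27). Ccl5 was at least 135-fold higher (7.28 ± 0.103) and Ccl12, which attracts monocytes, at least 75.7-fold higher (6.35 ± 0.097). Of 17 NF-kB pathway feedback genes 16 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.94, adjusted p = 2.94e-28), with Birc3 at 3.54 ± 0.066. Cytokines (15 higher and 3 lower of 37, 15 and 3 adjusted over the list alone, adjusted p = 2.81e-06) included Il1b, 76.2-fold higher, and Tnf at 0.45 (adjusted p = 1.59e-05). Pattern recognition and interleukin receptors (14 and 1 of 28, 14 and 1 adjusted over the list alone, adjusted p = 3.92e-06), JAK-STAT3 response genes (12 and 3 of 22, 12 and 3 adjusted over the list alone, adjusted p = 5.64e-06) and adhesion genes (9 and 3 of 18, 9 and 4 adjusted over the list alone, adjusted p = 0.00149) also stood higher, with Vcam1 at 5.10 ± 0.103. Of 25 eicosanoid and nitric oxide genes 13 rose and 1 fell (15 and 3 adjusted over the list alone, adjusted p = 2.24e-07), among them Ptges, the inducible prostaglandin E synthase (at least 5.14-fold), Pla2g2a, a secreted phospholipase (at least 7.24-fold), and Ass1, which recycles citrulline to arginine (4.37 ± 0.084). The p53 and cell death list rose in 11 of 25 cases and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 5.23e-05), with the death receptor Fas at 0.75 ± 0.07.

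Interferon response genes rose in 28 of 39 cases with 0 falls (31 and 0 adjusted over the list alone, adjusted p = 2.23e-18), but adjusted p = 0.0989 with an estimated correlation, and Mx1, an antiviral GTPase, stood at 3.27 ± 0.219. Complement and acute phase genes went both ways, 13 higher and 6 lower of 27 (14 and 6 adjusted over the list alone, adjusted p = 2.77e-05), with adjusted p = 0.13 with an estimated correlation. Higher were Cfb, the haemoglobin scavenger Hp (at least 13.2-fold), Orm1 (at least 10.1-fold) and the C1 inhibitor Serping1 (2.59 ± 0.094). The C1q chains C1qa (-1.59 ± 0.105), C1qb (-1.38 ± 0.148) and C1qc (-1.26 ± 0.109), made in brain mainly by microglia, were lower than in lacZ medium. Microglia and macrophage markers moved beside the antigen presentation, chemokine and complement genes: 23 of 37 were higher and 6 lower (23 and 6 adjusted over the list alone, median 0.44, adjusted p = 4.69e-07), with adjusted p = 0.125 with an estimated correlation. Adgre1, the macrophage surface protein F4/80, was higher by 4.13 ± 0.093 and Aif1, a calcium-binding protein of microglia, by 1.42 ± 0.188. The lipid receptor Trem2 was lower (-1.66 ± 0.138). Lower here is relative to lacZ medium at 24 h. From 6 h to 24 h in α-synuclein medium, 29 of 31 microglia markers above background rose and 2 fell.

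Cell cycle genes stood higher than in lacZ medium as a group, 70 higher and 0 lower of 81 (73 and 0 adjusted over the list alone, median 0.56, adjusted p = 4.59e-31). Examples were Ttk, a spindle checkpoint kinase (0.96 ± 0.07), cyclin A2 (Ccna2, 0.91 ± 0.089), the ubiquitin-conjugating enzyme Ube2c (0.87 ± 0.095) and the mitotic kinase Aurkb (0.85 ± 0.066). In both media the level of the list was lower at 24 h than at 6 h, as described below. Extracellular matrix genes fell in 16 of 37 cases and rose in 4 (19 and 5 adjusted over the list alone, adjusted p = 0.0173), but adjusted p = 0.215 with an estimated correlation. Outside that list, Ogn, another matrix proteoglycan (-1.95 ± 0.083), and Grem1, which blocks bone morphogenetic proteins (-2.83 ± 0.086), fell too. Heat shock and unfolded protein response genes fell in 11 of 44 cases and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.0035), with adjusted p = 0.0978 with an estimated correlation. The small heat shock proteins Cryab (-2.18 ± 0.085) and Hspb1 (-1.03 ± 0.061) were among them. Lysosome and autophagy genes fell in 10 of 36 cases and rose in 2 (13 and 2 adjusted over the list alone, adjusted p = 0.0258), with adjusted p = 0.159 with an estimated correlation.

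Reactive astrocyte lists were mixed at 24 h. Of 21 pan-reactive genes 10 rose and 5 fell (10 and 7 adjusted over the list alone, adjusted p = 0.0493), with adjusted p = 0.0989 with an estimated correlation. The call was also lost without lacZ 24 h replicate 3 (adjusted p = 0.052) or α-synuclein 24 h replicate 3 (adjusted p = 0.0623). Of 10 A1-type genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 0.00374), with adjusted p = 0.0989 with an estimated correlation. Gfap (-0.50 ± 0.068, adjusted p = 1.46e-05) and the filament gene Nes (-1.02 ± 0.069) fell, and Vim did not pass (-0.17 ± 0.06, adjusted p = 0.0511). The homeostatic astrocyte list did not pass (6 higher and 13 lower of 37, 6 and 15 adjusted over the list alone, adjusted p = 0.0626). Within it Aqp4 (0.93 ± 0.119), the glutamate transporter Slc1a2 (0.70 ± 0.083) and Clu (1.19 ± 0.096) rose, S100b fell (-1.19 ± 0.107), and the transporter Slc1a3 did not pass (-0.17, adjusted p = 0.177). Of the reference genes Gapdh stood at -0.01 (adjusted p = 0.981) and Actb at -0.25 (adjusted p = 0.00385).

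The remaining lists did not pass at 24 h. Higher and lower members numbered 10 and 6 of 29 matrix proteases and inhibitors (10 and 8 adjusted over the list alone, adjusted p = 0.0719), 5 and 10 of 41 antioxidant and NRF2 genes (5 and 10, adjusted p = 0.956) and 5 and 2 of 15 metallothioneins and metal handling genes (5 and 2, adjusted p = 0.0537). They numbered 7 and 13 of 35 immediate early genes (7 and 15 adjusted over the list alone, adjusted p = 0.108), 7 and 10 of 43 growth factors (7 and 11, adjusted p = 0.641) and 9 and 9 of 32 glycolysis and hypoxia genes (9 and 9, adjusted p = 0.124). Metabolic lists gave 5 and 5 of 29 cholesterol and fatty acid synthesis genes (7 and 6 adjusted over the list alone, adjusted p = 0.587) and 0 and 6 of 50 oxidative phosphorylation genes (0 and 3, adjusted p = 0.0749). Ribosomal proteins gave 1 and 0 of 54 (0 and 0 adjusted over the list alone, adjusted p = 0.328) and synuclein and related genes 0 and 2 of 11 (0 and 2, adjusted p = 0.448). Among markers of other cells, neuron markers gave 3 and 6 of 28 (3 and 6 adjusted over the list alone, adjusted p = 0.635), endothelial and mural markers 3 and 6 of 23 (3 and 6, adjusted p = 0.0626) and ependymal markers 0 and 2 of 11 (0 and 2, adjusted p = 0.898). Oligodendrocyte lineage markers gave 2 and 5 of 19 (2 and 6 adjusted over the list alone, adjusted p = 0.587), with a median of -0.07 and a mean of 0.11. Fibroblast and meningeal markers gave 4 and 8 of 22 (6 and 9 adjusted over the list alone, adjusted p = 0.639), with a median of -0.04 and a mean of 0.10. Without lacZ 24 h replicate 2, matrix proteases (adjusted p = 0.0484), metallothioneins (0.0414) and endothelial markers (0.0485) passed, and without α-synuclein 24 h replicate 2, metallothioneins (0.0286), oxidative phosphorylation (0.0436) and endothelial markers (0.0436) passed.

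**Figure D2:**
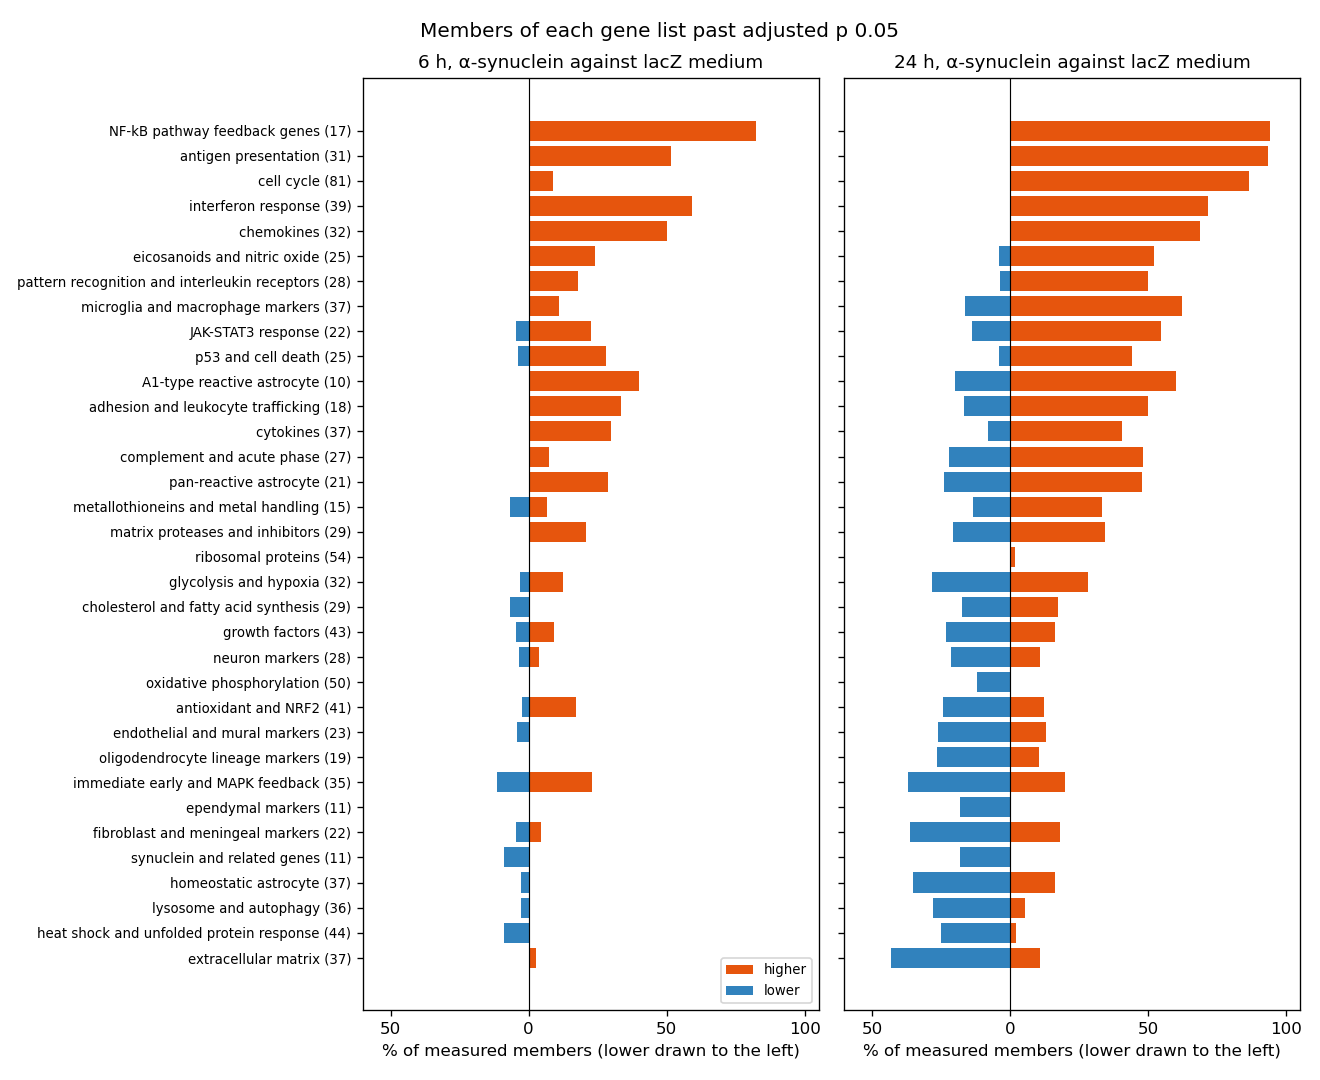
Percent of measured members higher (right) and lower (left) in α-synuclein than in lacZ medium at 6 h and 24 h for the 34 gene lists, counted over all probes. The NF-kB list had 14 of 17 members higher at 6 h and 16 at 24 h, and the cell cycle list 7 of 81 at 6 h and 70 at 24 h.

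The difference between the 24 h effect and the 6 h effect asks which effects were larger or smaller at 24 h than at 6 h. The lacZ cultures themselves differed between the times, as described below. A different mix of cells or different handling at 24 h therefore cannot be told apart from longer exposure here. Among named genes, the effect on Cfb was larger at 24 h by 5.86 ± 0.19 on the log2 scale (adjusted p = 1.2e-13), that on Ccl12 by 5.65 ± 0.137 (adjusted p = 2.3e-15), that on RT1-Da by 4.51 ± 0.117 (adjusted p = 3.92e-15) and that on Lcn2 by 4.35 ± 0.169 (adjusted p = 1.13e-12). The lacZ arrays of Ccl12 and RT1-Da lay at background at both times. Effects smaller at 24 h included those on Cxcl2 (-0.76 ± 0.124), Csf1 (-0.73 ± 0.121), the growth regulator Myc (-0.74 ± 0.086) and the MAP kinase phosphatase Dusp5 (-1.32 ± 0.115). Nfkbia (0.14 ± 0.116, adjusted p = 0.631) and the interferon-induced transcription factor Irf1 (0.04 ± 0.098, adjusted p = 0.914) did not pass this test. In all 2049 probes differed, 1024 upward and 1025 downward, 329 of them at least 2-fold. Of 34 lists 14 were called upward and 4 downward, and 7 of these held with an estimated correlation. Those 7 were cell cycle genes (52 upward and 0 downward of 81, 61 and 0 adjusted over the list alone, adjusted p = 1.52e-29), antigen presentation (24 and 0 of 31, 25 and 1 adjusted over the list alone, adjusted p = 2.63e-27), chemokines (16 and 1 of 32, 19 and 1 adjusted over the list alone, adjusted p = 1.9e-17), NF-kB feedback, pattern recognition, eicosanoids and JAK-STAT3 response genes.

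Most 6 h calls returned at 24 h. Of the 565 probes higher at 6 h, 433 (76.6%) were also higher at 24 h, where 47.4 would be shared if the calls were independent, and of the 399 lower at 6 h, 300 (75.2%) were also lower, against 43.6. Calls in opposite directions numbered 10 and 11; the urokinase gene Plau was higher at 6 h (0.93 ± 0.098) and lower at 24 h (-0.45 ± 0.098). The 2 comparisons share no arrays, but they share the same estimate of spread for each probe. A probe with a small spread is thus called more easily at both times. The expected counts also include the 45.3% of probes that never exceeded the background ceiling, which lowers them. The excess of shared calls over these counts is therefore not a measure of shared effect alone. Across probes, which are not independent replicates, the 6 h and 24 h changes correlated at r = 0.627 (Spearman's rho 0.307).

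**Figure D3:**
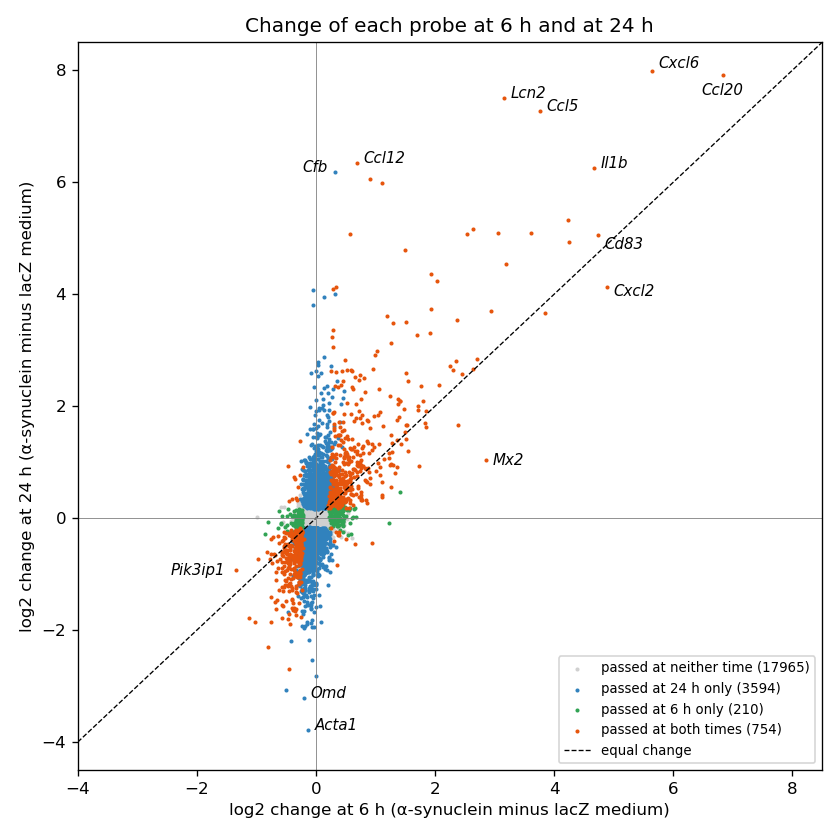
Log2 change in α-synuclein against lacZ medium at 6 h (horizontal) and 24 h (vertical) of 22523 probes, coloured by whether they were called at both times (754), at 6 h only (210), at 24 h only (3594) or at neither (17965). Ccl20 and Cxcl6 lie at the upper right, and Acta1 lies near 0 at 6 h and at -3.78 at 24 h.

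The time course in lacZ medium describes the control astrocytes between 6 h and 24 h. It shares its lacZ arrays with both treatment comparisons, so it is not independent of them. The oligodendrocyte marker list was called higher at 24 h and the cell cycle list lower. Bcas1, a gene of myelinating oligodendrocytes, rose by 3.18 ± 0.092 (n = 3 and 3, adjusted p = 2.01e-14), C1qb by 3.25 ± 0.148 (adjusted p = 4.17e-12) and Aif1 by 2.65 ± 0.188 (adjusted p = 1.65e-09). Elastin (Eln, -2.59 ± 0.108), the haem-degrading enzyme Hmox1 (-2.54 ± 0.099, adjusted p = 5.75e-13) and Ube2c (-2.42 ± 0.095) fell. In all 6802 probes changed, 3400 higher and 3402 lower at 24 h, 545 of them at least 2-fold. Of 81 cell cycle genes 70 fell and 1 rose (71 and 1 adjusted over the list alone, median -1.06, adjusted p = 1.75e-33). Oligodendrocyte lineage markers rose in 13 of 19 cases and fell in 1 (14 and 1 adjusted over the list alone, adjusted p = 1.71e-08), with the lineage factor Sox10 at 2.28 ± 0.074. Microglia markers rose in 25 of 37 cases and fell in 2 (28 and 2 adjusted over the list alone, adjusted p = 5.06e-12), with adjusted p = 0.118 with an estimated correlation. Neuron markers were called higher as well, 9 higher and 2 lower of 28 (9 and 2 adjusted over the list alone, adjusted p = 0.0483), with adjusted p = 0.119 with an estimated correlation. They lost the call without lacZ 6 h replicate 3 (adjusted p = 0.0536) or lacZ 24 h replicate 1 (adjusted p = 0.0658). Lysosome and autophagy genes rose beside the microglia markers, 21 higher and 2 lower of 36 (24 and 3 adjusted over the list alone, adjusted p = 0.000308), with adjusted p = 0.118 with an estimated correlation. Of the 10 lists called, 9 higher and 1 lower, the cell cycle and oligodendrocyte calls held with an estimated correlation.

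The same interval in α-synuclein medium shows the treated astrocytes. Cfb rose by 6.28 ± 0.134 (n = 3 and 3, adjusted p = 3.31e-17), Ccl12 by 6.16 ± 0.097 (adjusted p = 9.97e-19), Enpp2, the enzyme that makes lysophosphatidic acid, by 5.45 ± 0.117 (adjusted p = 3.31e-17) and Adgre1 32.1-fold (adjusted p = 4.37e-18). Grem1 (-4.81 ± 0.086), Acta1 (-4.51 ± 0.104) and Cryab (-3.69 ± 0.085) fell most. In all 7490 probes changed, 3547 higher and 3943 lower, 841 of them at least 2-fold. Microglia markers rose in 31 of 37 cases and fell in 2 (31 and 2 adjusted over the list alone, adjusted p = 9.79e-17), and antigen presentation genes rose in 24 of 31 and fell in 1 (26 and 1 adjusted over the list alone, adjusted p = 1.01e-13). Oligodendrocyte lineage markers rose in 12 of 19 and fell in 2 (13 and 2 adjusted over the list alone, adjusted p = 5.83e-07), with Bcas1 at 3.12 ± 0.092. Cell cycle genes fell in 57 of 81 cases and rose in 5 (58 and 9 adjusted over the list alone, median -0.58, adjusted p = 6.82e-12), with adjusted p = 0.0647 with an estimated correlation. Of the 20 lists called, 15 higher and 5 lower, 5 held with an estimated correlation: NF-kB feedback, pattern recognition, antigen presentation, microglia and oligodendrocyte.

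**Figure D4:**
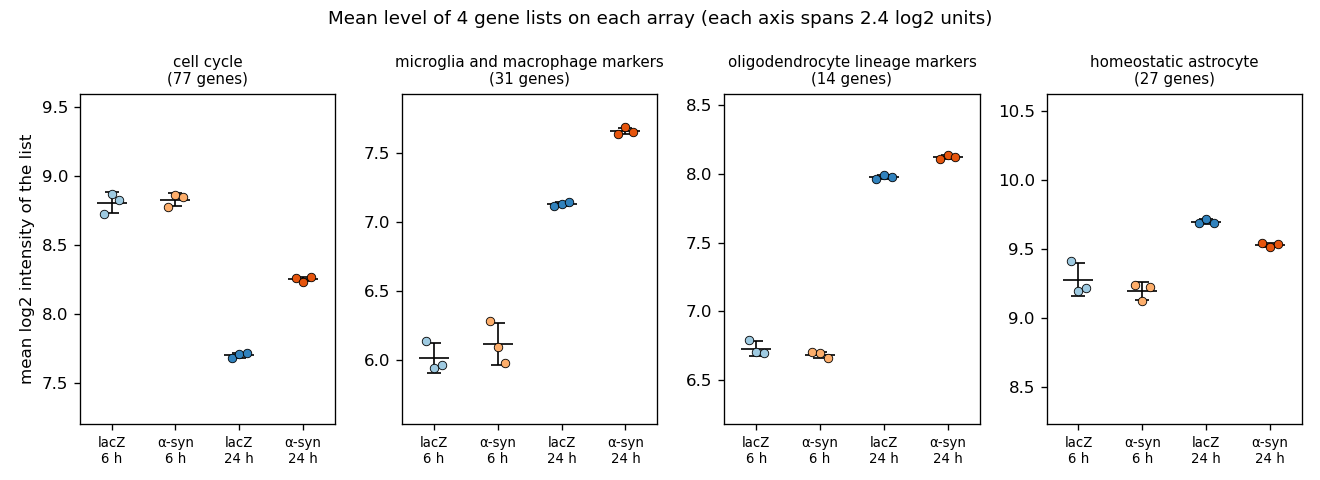
Mean log2 intensity per array (dots, 3 per group) over the members above background of the cell cycle (77 genes), microglia (31), oligodendrocyte (14) and homeostatic astrocyte (27) lists, in lacZ and α-synuclein medium at 6 h and 24 h. Cell cycle levels are lower at 24 h than at 6 h in both media, with a median change of -1.06 in lacZ and -0.58 in α-synuclein medium over all 81 measured genes.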

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

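The test of a different cell mix, both tests of the microglia share, the interval of the probe-pair test and the use of the members' own spread in the lag test were chosen only after the result was seen.

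The effect of α-synuclein medium differed between 24 h and 6 h for 2049 probes by limma's test of the difference itself. In this difference, longer exposure cannot be told apart from a different mix of cells or different handling at 6 h and 24 h. Regrouping the arrays within each time gave 5 of 100 splits, the real one included, with as many probes or more (highest other 2216). The 4 other splits as large kept the real grouping at 24 h and regrouped only the 6 h arrays, so they still hold the 24 h effect. This count therefore cannot decide about chance, which it does not exclude. Splits that regrouped the 24 h arrays called at most 3 probes. They mix the media within a group, so a real medium effect widens the spread and lowers such counts in advance. The splits of 3 against 3 arrays are 10 per comparison, too few for a share under 0.05; in each comparison the real split alone, 1 of 10, was as large. The real counts and the highest others were 964 and 69 at 6 h, 4348 and 0 at 24 h, 6802 and 0 for the lacZ time course, and 7490 and 0 for the α-synuclein time course. Regrouping widens the spread here in the same way, so the low counts of the other splits do not argue against chance.

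Differences are fitted log2 values, and where lacZ arrays lay at background they are not bounds. Named genes whose effect was more positive at 24 h than at 6 h were the chemokines Ccl12 (log2 difference 5.65), Ccl5 (3.51), Cxcl11 (2.53), Ccl4 (2.52), Cxcl6 (2.36), Cx3cl1 (1.34) and Ccl3 (1.11), and the interleukins Il1b (1.58) and Il1a (1.48). Acute phase, complement and antimicrobial genes were Cfb (5.86), Wfdc21 (4.88), Lcn2 (4.35), Orm1 (3.86) and Hp (3.82). Antigen presentation genes were RT1-Da (4.51) and Cd74 (2.75). Others were Chi3l1 (4.13), Asgr1 (3.8), Adgre1 (3.79), Pla2g2a (3.07), Vcam1 (2.03), Gbp5 (0.75), Slc1a2 (0.67) and Aqp4 (0.66). Aqp4 lost this call without lacZ 24 h replicate 3 (adjusted p = 0.0529) or α-synuclein 24 h replicate 3 (adjusted p = 0.0516). For Slitrk6 (0.58) and Pik3ip1 (0.41) the 24 h change lay nearer to 0 than the fall at 6 h. The effect was more negative at 24 h for Acta1 (-3.66), Omd (-3.01), Grem1 (-2.83), Arsi (-2.57), Sostdc1 (-2.24), Cryab (-2.07), Ogn (-1.92), Fgfbp1 (-1.77), Nkain4 (-1.76), Tgfb3 (-1.49), Fibin (-1.11) and Cxcr4 (-0.65). The rises of Mx2 (-1.81) and Cxcl2 (-0.76) were smaller at 24 h. The difference for Gfap (-0.32) lost its call without any of 9 arrays, all but lacZ 6 h replicate 1 and α-synuclein 6 h replicates 2 and 3, with adjusted p from 0.054 to 0.132. Without α-synuclein 6 h replicate 1 the difference for Mx2 was -1.23, and its change at 24 h lost its call without lacZ 24 h replicate 1 (adjusted p = 0.0581) or α-synuclein 24 h replicate 3 (adjusted p = 0.0739).

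Gene lists whose effect was more positive at 24 h had these median log2 differences: chemokines 0.91, antigen presentation 0.79, cell cycle 0.54, NF-kB feedback genes 0.46, eicosanoids and nitric oxide 0.15, JAK-STAT3 response 0.14 and pattern recognition 0.07, which also held with an estimated correlation. Calls lost with an estimated correlation, each with its adjusted p under that correlation, were microglia markers 0.37 (adjusted p = 0.136), complement and acute phase 0.18 (adjusted p = 0.113), interferon response 0.17 (adjusted p = 0.58), p53 and cell death 0.12 (adjusted p = 0.0844), metallothioneins 0.07 (adjusted p = 0.0892), glycolysis and hypoxia 0.04 (adjusted p = 0.104) and cytokines 0.04 (adjusted p = 0.113). The lists with a more negative effect lost their calls too: immediate early genes -0.35 (adjusted p = 0.0534), extracellular matrix -0.13 (adjusted p = 0.314), heat shock -0.11 (adjusted p = 0.136) and endothelial and mural markers -0.09 (adjusted p = 0.11). Some of these calls were also lost when 1 array was left out. The interferon call was lost without α-synuclein 6 h replicate 2 (adjusted p = 0.123) or 3 (0.157), and the matrix call without lacZ 6 h replicate 3 (0.0683) or α-synuclein 6 h replicate 3 (0.1). The heat shock call was lost without α-synuclein 6 h replicate 3 (0.0525). The endothelial call was lost without lacZ 6 h replicate 3, α-synuclein 6 h replicate 2, lacZ 24 h replicate 1 or α-synuclein 24 h replicate 1 (0.0528 to 0.0683). The glycolysis call was lost without lacZ 6 h replicate 3, α-synuclein 6 h replicate 1 or 2, lacZ 24 h replicate 2 or 3, or α-synuclein 24 h replicate 1 or 2 (0.0541 to 0.0857).

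In lacZ medium microglia and oligodendrocyte markers were higher and cell cycle genes lower at 24 h than at 6 h, with the microglia call lost at adjusted p = 0.118 with an estimated correlation. Neuron markers moved the same way (9 higher and 2 lower of 28, adjusted p = 0.0483), a call lost with an estimated correlation (adjusted p = 0.119) and without lacZ 6 h replicate 3 (0.0536) or lacZ 24 h replicate 1 (0.0658). A different mix of cells in the 6 h and 24 h cultures stays open: of 31 microglia markers above background, 25 rose and 2 fell, short of the 90% or more that a block would need and under the 10% of falls that would argue against it. A probe-level difference between the 6 h and 24 h arrays stays open as well, since the changes of 2 probes of the same gene correlated at 0.708 across 172 genes, just past the bound of 0.7 set beforehand but with a bootstrap interval of 0.635 to 0.841. Between the media, where no time difference enters, the same correlation was 0.646 at 6 h and 0.81 at 24 h. The bound thus cannot tell such a difference from other causes of a low correlation. A difference in handling between the 6 h and 24 h arrays cannot be told apart from time, because no array of the other time shares it. Time in the medium, which the design names, is an untested biological explanation.

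Microglia markers moved apart at 24 h between the media, with Adgre1 at 4.13 and Aif1 at 1.42 against C1qa at -1.59 and Trem2 at -1.66. Lower here means lower than in lacZ medium: from 6 h to 24 h in α-synuclein medium, 29 of 31 markers above background rose and 2 fell. Between the media at 24 h, 22 of the 31 were higher, which a lower share of microglia in the α-synuclein cultures would not produce as the whole cause. The 6 that were lower would not follow from a higher share as the whole cause. Both readings restate the counts that define the pattern, so neither is an independent test. A change of state of microglia, alone or together with a change of their share, may account for this pattern and was not tested, and how many of these markers astrocytes express was not measured here.

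Cell cycle genes were higher at 24 h in α-synuclein medium than in lacZ medium, after falling from 6 h to 24 h in both, with the call of the fall in α-synuclein medium lost at adjusted p = 0.0647 with an estimated correlation. If the α-synuclein cultures lagged behind the lacZ time course in general, genes that rose in lacZ medium would be short by a like share. The 42 cell cycle genes that fell at least 2-fold in lacZ medium missed a median of 39.1% of that fall (quartiles 34% to 49.8%). The 203 other genes that rose at least 2-fold missed a median of 15.3% of their rise (bootstrap interval of the median 4.2% to 24%), which met a bound set beforehand, but that bound left out the spread of the members, whose quartiles of -29.1% to 48.8% cover the cell cycle median, so a general lag stays open. An effect of α-synuclein medium on division may explain it and was not tested apart from the cell mix.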

How the results depend on the processing

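Leaving out the 2 arrays of lowest weight and keeping only probes above background were chosen after seeing the data. Of 40642 values of named genes under alternatives, 0 reversed, 38831 kept direction and side of the threshold, 1704 no longer passed and 107 newly passed. Most named genes were picked from these data by size of change or p-value, which makes reversals unlikely. Quantile normalization and median centring could change little, since the arrays were already normalized. Of 3380 list values, 4 reversed, 3173 stayed, 111 no longer passed and 92 newly passed. The 4 reversals all came with fry, whose direction differed from that given by camera. They were fibroblast markers at 24 h (median -0.038) and, in the α-synuclein time course, the pan-reactive (-0.181), p53 (-0.002) and fibroblast lists (-0.041). The cause was not tested.

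Counts of changed probes are given in the order 6 h, 24 h, difference between times, lacZ time course and α-synuclein time course. Requiring at least 1.5-fold left 213, 1214, 903, 1932 and 2526 by construction. Keeping only probes above the upper quartile of mean intensity, so that fewer were tested, gave 2284 at 24 h, 1133 for the difference, 3771 and 3966 in the time courses, and 12 lists in the α-synuclein time course. Only the arrays compared gave 538 at 6 h and an overlap of 458, and a plain two-sample test 67 at 6 h (65 shared) and an overlap of 58. Both use fewer arrays per estimate of spread. That alone does not account for the 538, since only the arrays compared gave more probes than the main fit at 24 h (5132 against 4348). The same fit gave 7005 against 6802 in the lacZ time course and 7177 against 7490 in the α-synuclein time course. With an estimated correlation 10, 7, 2 and 5 lists passed at 24 h, for the difference and in the lacZ and α-synuclein time courses. With fry, which does not compare a list with other genes, 30, 23 and 33 lists passed at 24 h and in the time courses, and with its mixed form 29, 33, 32, 34 and 34 in the order above.

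Leaving out each array in turn, with the spread pooled over groups, gave 718 to 1040, 3599 to 3884, 1721 to 2100, 6099 to 6628 and 6879 to 7223 probes, an overlap of 560 to 776, and 16 to 18, 17 to 21, 15 to 19, 9 to 11 and 19 to 21 lists. Replicate number as a block gave 976, 4353, 2068, 6817 and 7465 probes, of which 921, 4234, 1977, 6696 and 7367 were shared. Without the 2 arrays of lowest weight, lacZ 6 h replicate 1 and α-synuclein 6 h replicate 3, counts were 1384 (756 shared), 5180, 2337, 7162 and 7567, and over probes above background 1046, 4367, 2164, 6791 and 7322. The other alternatives stayed within 1.5 times each count. The offset on the log scale was not run, since the values are already log2, and the two-sample test and the fit to only the arrays compared have no form for the difference between times. Signal over background limits what can be called, since 45.3% of probes never exceeded the ceiling.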

Other observations

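Several genes not yet described at 24 h changed in α-synuclein medium. Sod2, the mitochondrial superoxide dismutase, rose by 3.60 ± 0.066 (log2, SE, n = 3 and 3), the iron carrier Tf by 2.33 ± 0.126 and Angptl4, an inhibitor of lipoprotein lipase, by 3.14 ± 0.086. Tgfb3, a transforming growth factor, fell (-2.30 ± 0.077), as did Cxcr4, the receptor for Cxcl12 (-1.41 ± 0.07), and Ackr3, which scavenges the same ligand (-0.60 ± 0.062). The glycoprotein Chi3l1, secreted by reactive astrocytes, rose by 4.08 ± 0.097, and Asgr1, best known as a liver receptor for asialoglycoproteins, by 4.09 ± 0.064. The phosphatase Dusp1 (-1.52 ± 0.071) and Fos (-1.12 ± 0.062) fell.

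Oligodendrocyte lineage genes went apart between the media at 24 h: Enpp2 (16-fold) and Pdgfra, the receptor that marks oligodendrocyte precursors (1.21 ± 0.077), rose in α-synuclein medium and the tight junction gene Cldn11 fell (-0.81 ± 0.081).

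In lacZ medium at 24 h, replicate 3 stood above the others for some chemokines: Ccl20 read 7.11 against 5.42 and 5.32, and Cxcl1 read 9.88 against 8.66 and 8.71. Without that array the 24 h change of Ccl20 was 8.495 instead of 7.92. Cxcl1 averaged 13.95 and 14.01 in α-synuclein medium at 6 h and 24 h, near the highest value of any probe, 14.21. For the ribosomal protein gene Rps9, chosen after its values were seen, the probes differed in size of change from 6 h to 24 h in lacZ medium, 4.84 for one and 1.58 for the other. Probes at or below the background ceiling on all arrays of one kind and more than 1 log2 unit above it on all of the other numbered 6 present only at 24 h and 0 only at 6 h, and 6 present only in α-synuclein medium and 0 only in lacZ medium.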
